A study of Mus musculus with 2 samples.

How the data were processed

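Pituitary total RNA was measured on 2 two-colour Agilent microarrays. Each array compared a pool of wild-type mice with a pool of mice homozygous for a disrupted Brdt gene, and each pool held RNA of 3 mice aged 8 weeks on a C57BL/6 background. The labels give 2 pools per genotype as biological replicates. They give the sex as male for the wild-type channel, and no sex for the knockout channel. On array 1 the wild-type pool carried Cy3 and the knockout pool Cy5, and on array 2 the dyes were exchanged. Per the labels' protocols, RNA was extracted with a phenol-based reagent, checked on a Bioanalyzer, and amplified and labelled with Agilent's low-input kit for 2 colours. The scanner settings, background correction and normalization are not given in the sources used here.

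The deposited values are signed linear fold changes, with 31840 rows in each of 2 columns and 1 row per gene name. The scale was read from the values: each was at or above 1 or at or below -1, and 0 lay in between. Each fold was converted to log2 of its size with its sign kept. The mean log2 ratio over all rows was -4.93e-05 on array 1 and -4.64e-05 on array 2, and whether the authors centred the values is not given in the sources used here. The median over gene rows as deposited was -0.03 on both arrays. How probes were combined per gene is unknown. Intensities were not used here, so no filter on dim probes could be set, and the number of arrays limits the precision. Agilent control features filled 56 rows and were left out, which left 31784 gene rows. Of these, 20794 carried a symbol of the mouse RefSeq annotation of assembly GRCm38.p6, 2749 matched through an older symbol, and 8241 had no match and kept the deposited name. That annotation served for names, gene classes and the neighbours of Brdt, and no coordinates are given because the authors' build is not given in the sources used here.

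No label or header states which channel stands over which. The rule fixed before the data were examined took both columns as knockout over wild type unless they correlated below -0.1 across genes. They correlated at 0.26, so that rule would have left array 2 as deposited. The main values depart from it. All 10 rows of Agilent's E1A spike-in RNAs had the same sign in both columns, which is what columns in the same dye order give if the spike-in mixtures went with the dyes, as in the manufacturer's design. That the mixtures were used that way is not stated in the sources used here. Both columns were therefore taken as Cy5 over Cy3, and array 2 was turned, so that values are knockout over wild type on both arrays. This choice was made after the columns and the spike-in rows were seen. The fixed rule is carried as an alternative for each main count. If both columns were instead Cy3 over Cy5, every direction given would invert.

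Each gene's log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, 1 residual degree of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. A sign-flip permutation of 2 arrays cannot give a two-sided p below 0.5. A dye term would have left no residual degrees of freedom, and a constant dye effect cancels in the mean of the turned arrays. Genes past 1.5-fold in the same direction on both arrays were counted and set against 1000 permutations of genes on array 2. For 32 gene lists fixed before the data were examined, limma's camera was run with a preset inter-gene correlation of 0.01, with an estimated correlation and on ranks, and fry was run beside it. The median of each list on each array was set against 10000 random lists of the same size, and 7 further lists were added after the data were seen. These percentiles ignore correlation between genes: 12 of the 32 fixed lists lay outside the central random lists in their median mean ratio, of which 5 passed camera with the preset correlation. Camera was therefore run on the added lists too, adjusted over the 7. Intervals marked ± are SDs over the 2 arrays.

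Named genes followed a rule fixed before the data were examined. It takes Brdt, up to 4 members per list with the largest mean log2 ratio in size, and 10 genes per direction ranked by the smaller of both arrays' ratios, since no gene passed the adjusted threshold. Predicted gene models were passed over in the ranking. Some genes that the rule takes are not reported here. A gene named outside this rule was chosen after its values were seen.

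The procedure was tested on simulated data with 31784 genes and the spread of these arrays. Each array's values were dealt to random genes, so neither the genes of a list nor the 2 arrays were correlated. Of 50 genes changed by a log2 of 1, limma called 0 at the adjusted threshold. It called 2 of 50 at a log2 of 2, 37 at 3 and 46 at 4. The fold count recovered 42 of the 50 genes changed by 1 and 50 of those changed by 2. Camera with the preset correlation called 20 of 20 lists of 15 genes shifted by 0.5, and 0 of 40 unshifted lists, while the estimated correlation and fry each called 0 of the 20 shifted lists. Since the simulated genes were uncorrelated, the 0 of 40 does not show how often camera calls an unshifted list of correlated genes. The alternatives covered the orientation, centring, spread, prior, fold threshold, genes counted, list test and each array alone. Figures were drawn with matplotlib 3.10.9.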

Results

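The data were 31784 gene-level ratios on each of 2 arrays that set pituitary RNA of Brdt-/- mice against that of wild-type mice. The allele is a knockout-first insertion, in which a reporter and selection cassette in an intron interrupts the gene. Brdt encodes a bromodomain protein of the BET family that is best known from male germ cells. The 2 wild-type and 2 knockout pools each held 3 mice, and each array paired 1 pool of each genotype, with the dyes exchanged on array 2. The comparison asks which pituitary transcripts differ between the genotypes. Values are log2 ratios of knockout over wild type, with array 1 given before array 2. That direction is likely rather than settled. It rests on the dyes in the labels, on the spike-in rows, and on the usual Cy5 over Cy3 convention. The spike-in rows place both columns in the same dye order only if their mixtures went with the dyes. That use is not stated in the sources used here. With the orientation rule fixed before the data were examined, array 2 keeps its deposited sign, and those counts are given beside the main ones.

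Brdt itself was at -0.30 on array 1 and -0.43 on array 2, a mean of -0.36 ± 0.10 (SD, n = 2). It did not pass limma's adjusted threshold (adjusted p = 0.999995). Without turning array 2 the mean was 0.07, so the sign depends on the orientation. The position of the probe relative to the cassette is not given in the sources used here, so the value does not establish loss of the transcript. Among the other BET family genes, Brd3 was at -0.16 and 0.15 and Brd2 at 0.08 and -0.06. Of 11 genes flanking Brdt, 3 were lower and 2 higher on both arrays, with Ephx4 at -1.02 and -0.32 and Cdc7, a kinase of replication origins, at -0.43 and -0.60. Neither list passed camera (adjusted p = 0.236 and 0.360).

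Immediate early genes, which respond within minutes to hormones and other stimuli, fell as a list in the knockout pools. Of 20 measured members, 14 were lower on both arrays and 1, Ier3, was higher on both. The list median was -0.26 on array 1 and -0.64 on array 2, and limma's camera gave an adjusted p of 1.45e-10 with the preset correlation and 0.872 with an estimated correlation. The orphan nuclear receptor genes Nr4a2 and Nr4a1 lay lowest, at -2.51 ± 0.30 (5.70-fold lower) and -2.02 ± 0.28 (4.07-fold lower; SD, n = 2 each). Atf3, a stress-induced transcription factor, was at -1.12 ± 0.11. These 3 genes passed when limma's p was adjusted over the list alone, and 0 passed over all genes. Egr1, a mediator of gonadotrophin-releasing hormone in gonadotrophs, was at -0.80 and -2.21, and Fos at -0.02 and -1.65, so array 2 carried most of their difference. Ier3 was at 0.92 and 0.20. With array 2 not turned the list median was 0.21 and camera's adjusted p was 0.163.

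**Figure D1:**
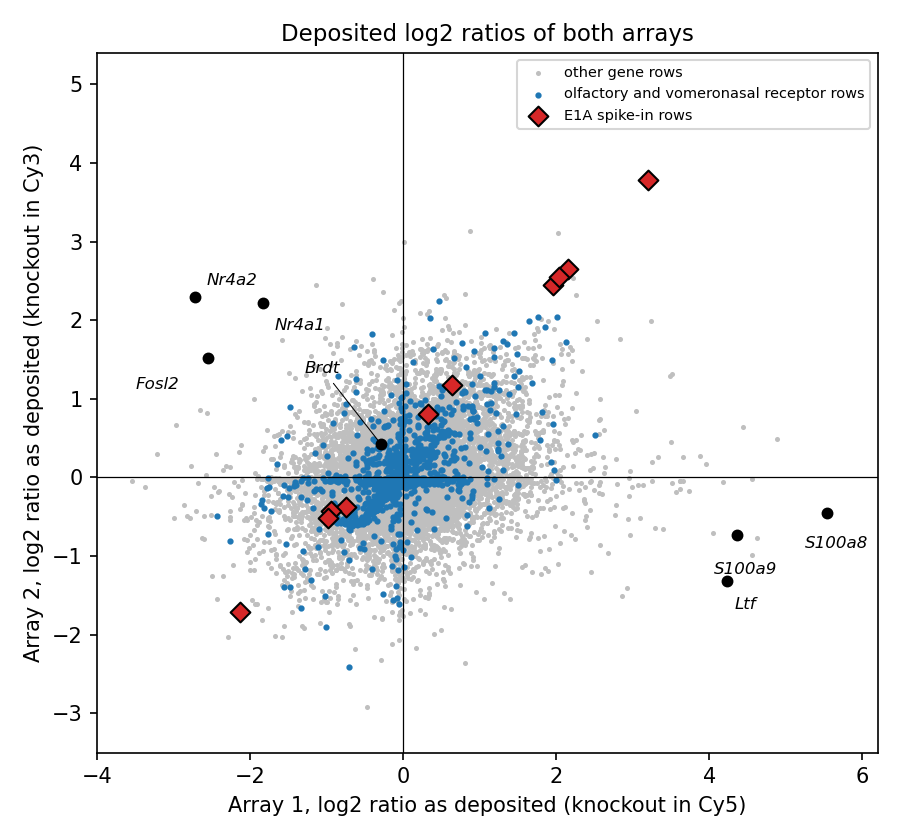
Each point is a gene row, with the deposited log2 ratio of array 1 on the horizontal axis and of array 2 on the vertical axis, before array 2 was turned; 1 gene row lies outside the axes. The 10 spike-in rows (red diamonds) have the same sign in both columns, whereas Nr4a2, Nr4a1 and Fosl2 at the upper left, and S100a8, S100a9 and Ltf at the lower right, have opposite signs, which become the same direction of knockout over wild type once the dyes are exchanged.

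Genes ranked lowest on both arrays included further stimulus-responsive genes. Fosl2, an AP-1 subunit, was at -2.55 and -1.52, Sik1, a kinase induced by cyclic AMP, at -1.21 and -1.55, and Gem, a small GTP-binding protein, at -1.49 and -1.33. Gdnf, a neurotrophic factor, was at -1.58 and -1.74. The other genes of this ranking were Mbl2 (-1.13 and -2.44), Ubd (-1.27 and -1.31), Hoxc12 (-1.41 and -1.26) and Coq10b (-1.22 and -1.14). Genes ranked highest included those of neutrophils, platelets and bone. Ltf, the neutrophil granule protein lactoferrin, was at 4.23 and 1.32, and Cebpe, a transcription factor of granulocyte maturation, at a mean of 1.83 ± 0.88 (SD, n = 2). The platelet chemokine gene Ppbp was at 2.86 and 1.51. The osteocalcin gene Bglap2 was at 1.56 and 1.14. Gdf10 (2.93 and 1.41), Foxl1 (1.81 and 1.22), Afm (1.85 and 1.15), Gabrg1 (1.59 and 1.11) and Ptgdr (1.05 and 1.54) were also in this ranking. None of the 20 ranked genes passed limma's adjusted threshold, and they were chosen for having the same sign on both turned arrays. With array 2 not turned, the sizes of their means ran from 0.02 to 1.45, with Nr4a2 at -0.21.

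**Figure D2:**
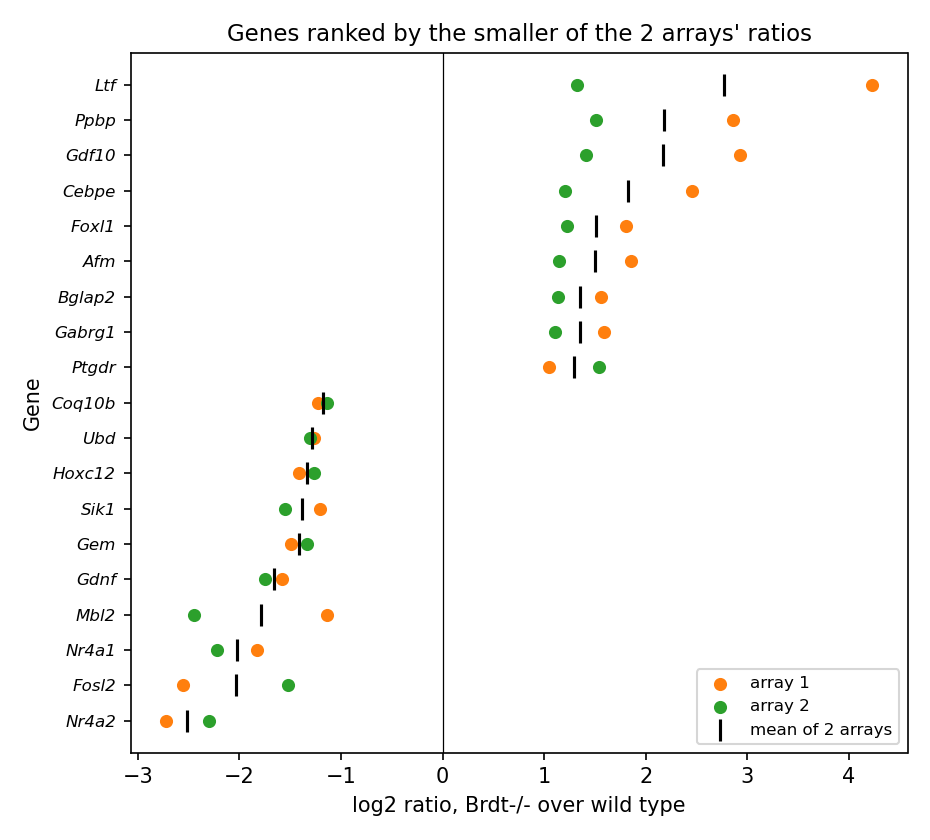
Log2 ratios of knockout over wild type on the horizontal axis for 19 of the ranked genes, with a point for each array and a bar at the mean. Nr4a2 has the lowest mean (-2.51) and Ltf the highest (2.77), and the arrays lie farther apart for Ltf than for Nr4a2.

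Immune cell genes rose as a list (14 members, 8 higher and 1 lower on both arrays), with medians of 0.42 and 0.17. Camera gave an adjusted p of 1.91e-04 with the preset correlation and 0.872 with an estimated correlation. The calprotectin genes S100a8 and S100a9, abundant in neutrophils, were at 5.54 and 4.36 on array 1 but 0.45 and 0.73 on array 2. Without them, an alternative chosen after seeing the data, the median of the mean ratios was 0.27 and limma's adjusted p 0.00277. The complement gene C1qa was at 0.25 and 0.50, and the antigen presentation genes H2-Aa and Cd74 at 0.64 and 0.09 and at 0.48 and 0.23. Red blood cell genes also rose as a list (5 members, 3 higher on both arrays), with medians of 0.12 and 1.16, so the median shifted mainly on array 2. Hba-a2 had the largest mean and was at 0.73 and 1.15, Hba-a1 was at -0.10 and 1.56, and Alas2, the erythroid enzyme of haem synthesis, at -0.08 and 1.53. Camera gave an adjusted p of 1.91e-04 for this list with the preset correlation and 0.872 with an estimated correlation. With array 2 not turned the immune list had an adjusted p of 0.294 and the red cell list one of 0.307.

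Cell cycle genes had a median of 0.50 on array 1 and -0.15 on array 2, and 10 of the 15 members had opposite signs. Camera called the list higher (adjusted p = 0.0209 with the preset correlation and 0.872 with an estimated correlation), and that call rested on array 1. Aurkb was at 1.13 and 0.00 and Bub1 at 0.84 and 0.15. Cytosolic ribosomal protein genes had medians of 0.02 and 0.13, with 58 of 142 members higher and 12 lower on both arrays (camera's adjusted p = 0.0463, and 0.872 with an estimated correlation). The name pattern of that list also took in 59 kinases, binding partners and pseudogenes, and without them, an alternative chosen after seeing the data, the adjusted p was 0.0126. The ribosomal list had a median of -0.064 and an adjusted p of 0.294 with array 2 not turned.

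The hormone genes of the anterior lobe did not shift as a list (7 members, medians 0.29 and -0.25, camera's adjusted p = 0.862). Pomc, the precursor of corticotrophin, was at -0.63 and -0.96, lower on both arrays. Fshb, the follicle-stimulating hormone subunit, was at 0.29 and 0.52, higher on both. Gh was at 0.43 and -0.65, Cga at 0.91 and -0.25 and Lhb at -0.10 and 0.30, each with opposite signs on the arrays. These signs hold for the turned array 2. In the other orientation 4 of the 7 hormone genes were higher and 1, Lhb, was lower on both arrays, and the list had a median of 0.17 and an adjusted p of 0.121. Among the endocrine cell lists, camera's adjusted p was 0.113 for gonadotrophs, 0.141 for somatotrophs, 0.739 for corticotrophs and melanotrophs, 0.692 for thyrotrophs and 0.945 for lactotrophs. In the corticotroph list Tbx19 and Crhr1 were at 0.39 and 0.30 and at 0.41 and 0.31, the opposite sign to Pomc. The ghrelin receptor gene Ghsr was at -0.60 and -0.94.

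**Figure D3:**
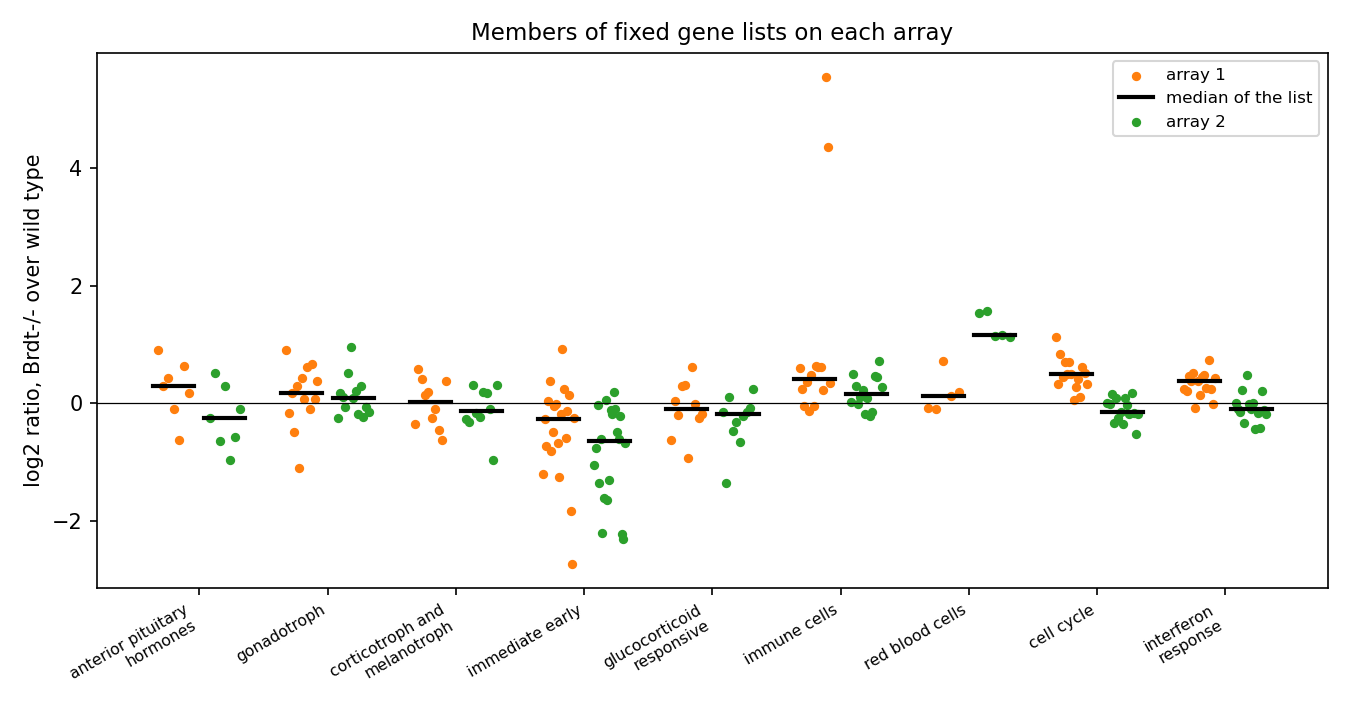
Log2 ratios of knockout over wild type on the vertical axis for the measured members of 9 gene lists, each gene drawn once per array, with a bar at the list median. The immediate early medians lie below 0 on both arrays (-0.26 and -0.64), the red blood cell median departs from 0 mainly on array 2 (1.16), and the cell cycle medians have opposite signs (0.50 and -0.15).

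Other cell types that a dissected pituitary could hold did not pass camera. The adjusted p was 0.213 for stem and folliculostellate cells, 0.275 for pituicytes, 0.692 for hypothalamic and neural axon transcripts, 0.945 for endothelial cells, 0.859 for fibroblasts and pericytes, 0.184 for skeletal muscle and 0.113 for cartilage and bone. Members with the same sign on both arrays included Ckm, the muscle creatine kinase, at -0.95 and -1.43, Comp of cartilage at 0.75 and 0.96, and Avp at 0.57 and 0.41, none of which passed limma's test, adjusted over the list alone or over all genes. The sex-linked list gave an adjusted p of 0.859, with Xist at 0.67 and 0.03. The Y-linked genes did not move one way: Kdm5d was at -0.21 and -0.52, Eif2s3y at 0.46 and -0.11, Uty at 0.15 and -0.28 and Ddx3y at -0.03 and -0.21. Germ cell genes gave an adjusted p of 0.184, with the protamine gene Prm1 at -1.07 and -0.57 and Sycp3 at 0.65 and 0.32.

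Among the pathway lists that did not pass, the adjusted p was 0.0762 for each of glucocorticoid-responsive, interferon, heat shock and respiratory chain genes. Per1, a clock gene that glucocorticoids also induce, was at -0.92 and -0.66, and Dnajb1 at -0.64 and -0.20. The clock list gave 0.945, with medians of 0.26 and -0.23 and Nr1d1 at 1.02 and 0.18. Cholesterol synthesis gave 0.113, with Insig1 at -0.38 and -0.43 and Cyp51 at -0.24 and -0.40. Camera's adjusted p was 0.325 for sex steroid receptors and oestrogen-responsive genes, 0.602 for replication-dependent histones, 0.692 for secretory granule genes and 0.141 for interleukins and chemokines. With array 2 not turned, 3 lists passed camera: the clock (median 0.28, adjusted p = 0.00903), interferon (0.20, adjusted p = 0.00362) and cell cycle lists (0.35, adjusted p = 7.26e-04). All 3 calls were lost with an estimated correlation (adjusted p = 0.904 each).

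Across the array, 0 of 31784 genes passed limma's adjusted threshold in either orientation. At limma's unadjusted p under 0.05, 703 genes passed (326 higher and 377 lower), and 3254 passed with array 2 not turned. Uniform p-values would give 1589.2. In the simulation, where the arrays were uncorrelated, 714 unchanged genes (2.26%) passed. The 703 genes lie close to that count, but the real turned arrays were correlated at -0.26 across genes. The simulation therefore does not give the count for unchanged genes in these data, and no excess or deficit is read from it. Past 1.5-fold in the same direction on both arrays were 258 genes (114 higher and 144 lower), against a mean of 199.4 when genes were permuted on array 2 (central range 174 to 228). That permutation treats genes as independent and is no measure of what 2 arrays without a genotype effect would give. With array 2 not turned there were 1008 (644 positive and 364 negative), against 203.9 with permuted genes. Array 1 alone had 4393 genes past 1.5-fold and array 2 had 2921. Across genes, which are not independent replicates, Pearson's r between the turned arrays was -0.26 and Spearman's rho -0.22. With 2 arrays, limma called 0 of 50 simulated genes changed by a log2 of 1, so differences of that size were not detectable here by the adjusted test.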

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

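The tests of this part were chosen after the result was seen. The E1A spike-in rows, control features outside the comparison, carried a signal of 1.58 in mean log2 size over both arrays, against 0.0675 for the single negative control row. All 10 had the same sign in both deposited columns (r = 0.9997), and array 2 lay above array 1 by 0.49 ± 0.06 (SD over the 10 rows).

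Across gene rows the deposited columns also tended to have the same sign, although the knockout pool was in opposite dyes. A candidate explanation is a bias of each feature towards a dye, with both columns in the same dye order. Over 1374 olfactory and vomeronasal receptor rows, genes that a pituitary is not known to use, r between the deposited columns was 0.52, above the 0.19 of the other protein-coding genes, which is what such a bias predicts. The other reading, that both columns run knockout over wild type, predicts that gene lists shift the same way in both deposited columns. Of 6 lists outside the central range of random lists in both columns, 3 lay on opposite sides (immune cells, immediate early genes and ribosomal proteins) and 3 on the same side (hormones, clock and cell cycle), so this test left both readings open. A genotype effect on the latter 3 lists also stays open, and no direction in the report is settled beyond the spike-in evidence.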

How the results depend on the processing

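Alternatives with the protein-coding genes or reduced lists, without the extreme row, and Spearman's rho were chosen after seeing the data. Centring and scaling kept Brdt, the fold count (264 and 270) and the 5 called lists on their side. With array 2 not turned, the orientation fixed beforehand, Brdt moved to 0.067, r to 0.26, the fold count to 1008 and the called lists to 3. The list medians reversed to -0.52 for red blood cells, 0.21 for immediate early genes and -0.064 for ribosomal proteins. These follow from the turned sign itself. The fold count was 1696 at 1.2-fold, 36 at 2-fold and 137 over protein-coding genes without receptors, fewer by construction with a higher threshold or fewer genes, and 2921 to 4393 on a single array, where no second array has to agree. The gene count of 0 became 703 at an unadjusted p. The ordinary one-sample statistic called 2, Ccdc107 and Kri1, which had identical ratios on both arrays (-0.01 and -0.09) and so an SD of 0. Camera called 0 lists with an estimated correlation and 8 on ranks, adding interferon, heat shock and respiratory chain, and fry called 0. Both methods that called 0 also missed all 20 shifted lists of the simulation, so they do not speak to stability. The cell cycle median ranged from -0.15 to 0.50 over single arrays. The cause of the other changes was not tested. Not run were a choice among probes (1 row per gene was given), another log base (the folds are linear) and a leave-one-out test of the gene count (no residual degrees of freedom). The main test is itself paired, since each array sets 1 pool of each genotype against the other. Signal over background is unknown, so dim genes could not be set apart.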

Other observations

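The gene lists of this part were added after the data were seen. The tests of blood and of dye bias were chosen after their results were seen, while those of cyclic AMP signalling and of bone marrow were written before. Of 19 mature neutrophil genes 17 were higher on both arrays, with medians of 2.32 and 0.45 (camera's adjusted p = 1.20e-11 with the preset correlation and 0.551 with an estimated correlation). That list holds S100a8, S100a9 and Ltf, which had been seen to be high before it was written. Without these genes 14 of 16 were higher on both arrays, the medians were 1.74 and 0.31, and camera gave a p of 3.94e-10 with the preset correlation and 0.227 with an estimated correlation. On array 1, 11 of the 19 were above a log2 of 2, led by S100a8 (5.54), S100a9 (4.36), Ltf (4.23), Camp (3.62) and Ngp (3.30), and on array 2 the count was 0. Other members lay nearer 0 on array 1, with Csf3r at -0.27 and -0.14 and Cxcr2 at 0.05 and 1.24. Padi4 was at 0.12 and 0.13 and Hdc at 0.17 and -0.13. Platelet genes had medians of 0.50 and 0.32, with Clec1b at 0.88 and 1.13, Pf4 at 0.89 and 0.35 and Gp1bb at 0.24 and -1.63 (camera's adjusted p = 3.78e-04, and 0.551 with an estimated correlation). Without Ppbp, a member already seen in the ranking, the medians were 0.45 and 0.28 and limma's camera gave an unadjusted p of 0.00480, or 0.211 with an estimated correlation. Osteoblast and osteoclast genes had medians of 0.37 and 0.04, with Alpl at 0.76 and 0.87 but Runx2 at -0.62 and -0.47 and Sp7 at 0.95 and -0.96 (camera's adjusted p = 0.00527, and 0.575 with an estimated correlation). Without Bglap2 and Bglap, also seen beforehand, the medians were 0.25 and 0.01 and the list did not pass limma's camera (unadjusted p = 0.123, or 0.423 with an estimated correlation). These values, too, hold for the turned array 2. Left as deposited, 1 of 19 neutrophil genes was higher on both arrays, and camera's adjusted p with the preset correlation was 0.0771 for the neutrophil, 0.330 for the platelet and 0.103 for the bone list. Erythroid precursor genes had medians of -0.15 and 0.19. The row C630016N16Rik had a deposited fold of 1358.83 on array 1 and 1.00 on array 2.

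The neutrophil signal of knockout pool 1 might come from blood or marrow in the tissue. If peripheral blood left in the tissue were the source, haemoglobin genes on array 1 would be higher by a similar amount. The neutrophil median exceeded the haemoglobin median (0.16) by 2.17. The members' median absolute deviation was 2.28 after R's default scaling to the SD of a normal distribution. By the criterion set for this test, computed that way, blood could not be excluded. The unscaled deviation was smaller than 2.17, so that outcome rests on the scaling, which the criterion did not name. After that outcome a further count was made, as a description that decides nothing: 13 of the 19 neutrophil genes lay above the highest haemoglobin gene (0.73). Bone marrow carried over from the skull base predicts higher granule precursor and B-cell precursor genes. The granule precursor list lay at percentile 100 of random lists on array 1 (median 2.37, with Mpo at 3.50 and Ms4a3 at 3.14), while its median on array 2 was -0.12. Its members Elane and Epx were at -0.09 and 0.54 on array 1. Camera gave this list an adjusted p of 3.29e-04 with the preset correlation and 0.599 with an estimated correlation. With array 2 left as deposited the list had a median of 1.38, and 5 of 10 members were higher on both arrays. In that orientation the list still passed camera with the preset correlation (adjusted p = 0.00479), but not with an estimated correlation (0.740). It holds Cebpe and Gfi1, seen beforehand, and without them the array 1 median was 2.17. The B-cell precursor list lay at percentile 16.09 on array 1 (median -0.11, median absolute deviation 0.56 with the same scaling). Its members went both ways, with 3 of 12 higher, and the highest, Rag1 at 0.49, lay far below the granule precursor median, which argues against whole marrow as the source. Blood hardly holds granule precursor genes, so blood alone would not predict their array 1 median of 2.37. That was not set as a test of blood and rests on 1 array. The B-cell precursor list cannot exclude marrow poor in B-cell precursors or bone tissue. On array 1 the osteoblast and osteoclast list lay at percentile 99.91 and the platelet list at 99.94, while erythroid precursor genes lay at 9.26. With these limits, blood, such marrow or bone tissue, a granulocytic infiltrate in some mouse of the pool and the genotype stay open.

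For the lower immediate early genes, the column orientation stays open, as do genotype and handling before collection. With both columns in the same dye order, a dye bias equal on both arrays cancels in the mean and would not account for the lower values. Whether the bias was equal was not tested, and the spike-in rows lay higher on array 2 by a mean of 0.49. The list lay at percentile 0.08 of random lists in deposited column 1 and 100 in column 2, which restates the pattern and does not test the orientation. If both columns run knockout over wild type, the list is not lower on both arrays, and a dye bias could give these opposite values. Weaker cAMP and CREB signalling in the knockout pools at collection predicts that other genes induced by cyclic AMP are lower too. A list of 20 such genes outside the immediate early list had a median of -0.29, at percentile 0 of random lists, a measure that also set apart 12 of the 32 fixed lists. Camera gave it an adjusted p of 3.90e-06 with the preset correlation and 0.551 with an estimated correlation. Of its members, 13 were lower on both arrays, 2 were higher on both and 5 had opposite signs. Arc (-1.10 and -0.86), Crem (-1.07 and -0.52) and Irs2 (-0.45 and -0.54) were among the lower ones. Ptgs2 (0.05 and -0.02) and Ppargc1a (-0.15 and -0.12) lay near 0. With array 2 left as deposited this list had a median of 0.04 (percentile 88.2) and camera's adjusted p was 0.698, so the hypothesis that this signalling was weaker may be followed up only if the turned orientation is right. These genes also respond to other stimuli, some of them, such as Arc, together with immediate early genes. The shift of the list therefore cannot single out this signalling. Genotype and handling before collection were not separated by the design, and with array 2 not turned the immediate early median was 0.21.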
